A study of Mus musculus with 45 samples.

How the data were processed

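The series holds 45 samples of mouse (C57BL/6) bone-marrow-derived macrophages, taken on day 7 of differentiation in L929-conditioned medium. Poly(A) RNA of 21 libraries was analysed, in 7 groups of 3: untreated cells, and cells given IL-4 (10 ng/ml), IFN-γ (100 ng/ml) or both for 2 h or 4 h. The other 24 libraries come from cells with short hairpin RNAs and are not analysed here.

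The deposited table gives CPM (reads of a gene scaled to the total of the library) for 24421 genes in these 21 libraries. Per the labels, reads were aligned with TopHat2 2.1.0, counted with HTSeq and processed with edgeR, on the mouse build mm10 (GRCm38); no further settings were given. Each library's smallest value above 0 was taken as 1 read. All values (100%) were then whole numbers of reads within 0.01 read, and totals ran from 28920801 reads (untreated replicate 2) to 80028327 reads (untreated replicate 3). One read was 0.0125 to 0.0346 CPM, and 5857 genes had no reads in any library. GENCODE vM21 named 23376 of the gene symbols, and 24335 were found with RefSeq symbols and synonyms added; coordinates come from GENCODE vM21 on GRCm38.

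Genes with at least 1 CPM in at least 3 libraries were tested (11380). The values were taken as log2(CPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (1 mean per group, 14 residual degrees of freedom, empirical Bayes with a trend). P-values were adjusted within each contrast by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The labels do not say whether replicates came from separate animals or cultures, and p-values then measure only the spread between these samples, which may be technical. There were 15 contrasts. They set each treatment against untreated cells, the combination against each single cytokine, and 4 h against 2 h. A further pair, 1 per time point, tested the interaction, the change under the combination minus the sum of the changes under the single cytokines.

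Untreated replicates 2 and 3 carried many reads of ribosomal RNA, which lower the CPM of all other genes. Counts of called genes come from the deposited values, with the count after median-ratio rescaling beside them. Log2 changes, standard errors, adjusted p and CPM of single genes come from the rescaled values. A gene is said to have risen or fallen only where both fits called it in the same direction. Unless a sentence says otherwise, a value after ± is the standard error of a log2 change or the standard deviation of CPM, with n = 3 libraries per group.

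A gene counted as induced by a cytokine when it was called with a log2 change of at least 1 against untreated cells. The induced genes were then divided by their call between the combination and that cytokine. The libraries of that cytokine enter both steps, so noise in the selection favours a lower call under the combination. As an alternative the genes were selected at the other time point, which shares no library with the second step. Genes called under both single cytokines at 4 h were sorted into the same and the opposite direction, against the products of the call rates. As both responses share untreated libraries, a simulation without treatment effect (20 runs) gave the covariance that sharing alone makes. A second one, added after seeing the data, also kept the mean of each replicate number and used the spread left by the block.

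Gene lists fixed before the files were opened were tested with fry, which asks whether the members of a list move one way on balance, and with camera at a correlation estimated from the data. Their p values come from the deposited values without the block, unless a sentence names rescaled values or the block. In the deposited values the median log2 change over all genes was 0.10 to 0.43 against untreated cells. For the interaction it was -0.40 at 2 h and -0.38 at 4 h. The fry test is against no change, so its p values, and list counts as deposited, include that shift in these contrasts. A list needed 3 measured members. The lists covered markers of alternative and of classical activation, guanylate-binding proteins with immunity-related GTPases, genes classically induced by type I interferon, and both MHC classes. Others held cytokines with chemokines, chemokine receptors, JAK-STAT components, AP-1 with C/EBP factors, interferon regulatory factors, MYC with ribosome biogenesis, cholesterol synthesis, lipid handling, glycolysis, DNA replication, mitosis and macrophage identity. The rest held pattern recognition, adhesion with matrix, heat shock with stress, immediate early genes, mitochondrially encoded genes, histones and markers of 8 other cell types.

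Genes were named by a rule. It took 8 fixed factors and 7 fixed markers, and the 10 largest changes in each direction with at least 5 CPM and no overlap between the libraries of both groups. It added up to 4 called and 2 uncalled members of each list, 10 lowered and 6 other induced genes, and 6 opposed genes per direction. Predicted genes, RIKEN clones and pseudogenes were left out. The text names part of these genes.

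The sample groups, contrasts, lists, naming rule and alternative settings were chosen before the data were examined. The alternatives were a pseudocount of 0.1, no filter on low values (18564 genes), a mean of at least 5 CPM (9275 genes), median-ratio scaling, quantile normalization, the replicate number as a fixed factor (block), edgeR 4.0.16, DESeq2 1.42.0, a log2 change of at least 1, only the groups of each contrast, and leaving out each library and each replicate number. The block with rescaled values, untreated replicate 1 as the lone control and the rescaled list tests were added after seeing the data.

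Tested on simulated data with 200 changed genes among 11380, limma recovered 101 (35 of 67 at 2-fold and 61 of 66 at 4-fold) and called 5 unchanged genes. On rescaled values it recovered 108, also with 5 unchanged genes called. DESeq2 recovered 128 and called 33 unchanged genes. The simulated libraries varied independently and held neither the ribosomal RNA of untreated cells nor shared differences between replicate numbers. These counts therefore do not show how many false calls those features make in the real data. Differences between libraries of 1 group exceeded counting error, with chi-square per degree of freedom from 58.1 to 420 in the treated groups and from 758.4 to 2164 in untreated cells, where the libraries differed in ribosomal RNA.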

Results

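The libraries held 14688 to 16161 genes above 0. Rn45s, the precursor of ribosomal RNA, took 0.151%, 43.2% and 15.7% of the assigned reads in untreated replicates 1, 2 and 3. Lars2, a mitochondrial tRNA synthetase gene, took 0.120%, 7.42% and 2.76%. The highest Rn45s share in a treated library was 3.21% (combination, 4 h, replicate 3). Median-ratio factors ran from 0.573 (untreated replicate 2) to 1.22 (IL-4, 4 h, replicate 2). Libraries with the same replicate number resembled each other across groups: with group means removed, the 63 pairs with 1 number correlated across genes at 0.522 to 0.951, and pairs with different numbers at 0.374 or less. The first 4 principal components held 41.7%, 23.1%, 15.7% and 7.41% of the variance.

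**Figure D1:**
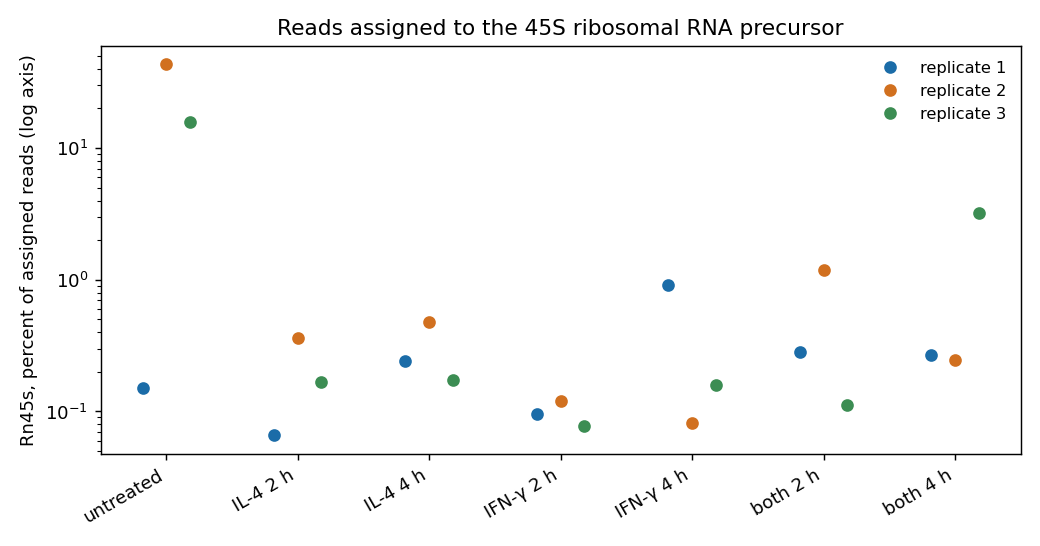
Percent of assigned reads on Rn45s (y axis, log scale) in each of the 21 libraries (x axis, by group, 1 point per library). Untreated replicates 2 and 3 lie at 43.2% and 15.7%, and the highest treated library at 3.21%.

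At 2 h, IL-4 raised Socs1, which encodes a feedback inhibitor of JAK signalling, from 0.890 ± 0.396 to 86.2 ± 29.1 CPM (log2 change 5.50 ± 0.22, adjusted p = 1.1e-10; chromosome 16, 10782240 to 10785536, GRCm38, GENCODE vM21). Cish (5.11 ± 0.35) and Socs2 (4.22 ± 0.23), of the same inhibitor family, rose with it. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, rose from 0.242 ± 0.0621 to 25.1 ± 5.06 CPM (4.38 ± 0.31, adjusted p = 8.2e-08). Irf4, an interferon regulatory factor of the IL-4 response, rose by log2 3.10 ± 0.31, adjusted p = 3.9e-06. Further increases were seen for Rasgrp1 (a Ras exchange factor, 5.29 ± 0.38), Tmem26 (a membrane protein of unknown role, 3.96 ± 0.17), Nfil3 (a bZIP repressor, 3.32 ± 0.32), Dusp4 (a MAP kinase phosphatase, 3.32 ± 0.31) and Slc7a2 (an arginine carrier, 3.25 ± 0.34). Egr2, an early growth response factor, varied more (3.77 ± 0.85, adjusted p = 0.0083), as did Arg1, the arginase of alternative activation (9.69 ± 6.38 CPM; 2.95 ± 0.60, adjusted p = 0.0041). Of the 32 measured markers of alternative activation, 18 rose, among them Klf4 (a zinc-finger factor, 2.82 ± 0.28), Il4ra (the IL-4 receptor chain, 2.04 ± 0.26) and Mrc1 (the mannose receptor, 1.20 ± 0.18). As deposited 20 were higher and 22 adjusted over the list alone (fry adjusted p = 8.3e-08; adjusted p = 0.048 with an estimated correlation). MYC with ribosome biogenesis had 15 of 35 members up, such as Myc itself (3.32 ± 0.23), Rrs1 (1.23 ± 0.22) and Ppan (1.14 ± 0.13). As deposited 24 were higher and 31 adjusted over the list alone (fry adjusted p = 0.0012; adjusted p = 0.7 with an estimated correlation). JAK-STAT components had 6 of 24 up (fry adjusted p = 1.6e-04; adjusted p = 0.7 with an estimated correlation). Among the decreases were Kcnj2 (a potassium channel, -3.26 ± 0.34), Nfkbiz (an atypical inhibitor of NF-κB, -2.87 ± 0.43), Arrdc3 (an arrestin relative, -2.77 ± 0.23) and Thbs1 (thrombospondin, -2.40 ± 0.34). The calls of Egr2 (adjusted p = 0.11) and Thbs1 (0.15) were lost without replicate 3 in all groups, and with untreated replicate 1 as the lone control those of Egr2 (0.19), Arg1 (0.065) and Rrs1 (0.085). In the deposited values 1833 genes were higher and 70 lower, with a median log2 change of 0.39 over all genes. The list counts as deposited and the fry p values above include this shift. After rescaling 597 were higher and 385 lower, and with the replicate number as a block 4124 and 214. The total of 1903 became 5760 without untreated replicate 1, 979 without untreated replicate 2, and 925, 877 and 1134 without IL-4 replicates 1, 2 and 3. It became 1179 without replicate 2 and 251 without replicate 3 in all groups.

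At 4 h, Retnla, which encodes the secreted protein RELMα, had no reads in untreated cells and 43.8 ± 4.17 CPM under IL-4, an increase of at least 1848-fold (chromosome 16, 48842551 to 48844461). At 2 h it stood at 1.49 CPM, at least 62.8-fold. The floor of both folds is 3 reads over the untreated group, rescaled like the other values. Pdcd1lg2 reached 80.7 ± 13.8 CPM (6.03 ± 0.31, adjusted p = 8.0e-10; chromosome 19, 29410919 to 29471161) and Tmem26 91.4 ± 11.5 CPM (6.27 ± 0.17, adjusted p = 1.9e-13). Arg1 rose to 64.2 ± 70.8 CPM, a spread larger than its mean (5.15 ± 0.60, adjusted p = 9.1e-06; chromosome 10, 24915221 to 24927484). Ccl24, an eosinophil chemokine, rose by log2 4.74 ± 0.54, adjusted p = 7.4e-06, and Ccl7, a monocyte chemokine, by 4.97 ± 0.83. Irf4 (3.46 ± 0.31; chromosome 13, 30749226 to 30766976), Batf3 (a bZIP factor, 3.43 ± 0.30) and Cdh1 (E-cadherin, 3.37 ± 0.19) rose as well. Chil3, which encodes a chitinase-like protein used as a marker of IL-4, was not called (1.01 ± 0.61, adjusted p = 0.28; adjusted p = 5.4e-05 with the block on rescaled values). The call of Stat6, the transcription factor downstream of the IL-4 receptor, depended on the scaling: the log2 change was 0.10 as deposited (adjusted p = 0.69) and -0.40 ± 0.13 after rescaling (adjusted p = 0.03, and 2.7e-04 with the block). Markers of alternative activation had 22 of 32 members up, Il4ra (2.33 ± 0.26) and Mrc1 (1.71 ± 0.18) included; 26 were higher as deposited and 28 adjusted over the list alone (fry adjusted p = 6.8e-10; adjusted p = 0.036 with an estimated correlation). MYC with ribosome biogenesis had 29 of 35 up, for example Myc (3.06 ± 0.23), Srm (spermidine synthase, 1.98 ± 0.19), Nolc1 (1.42 ± 0.19) and Gnl3 (1.41 ± 0.20), both nucleolar. As deposited 32 were higher, 33 adjusted over the list alone (fry adjusted p = 5.6e-05; adjusted p = 0.78 with an estimated correlation). Chemokine receptors had 5 of 12 down and 0 up, 6 adjusted over the list alone (fry adjusted p = 0.0031; adjusted p = 0.036 with an estimated correlation). Ccr2 (-2.56 ± 0.47), Cx3cr1 (-2.77 ± 0.46) and C5ar1 (-2.14 ± 0.19), receptors for chemokines and complement, were among them. Slc40a1 (the iron exporter, -3.00 ± 0.33), Tlr13 (a receptor for bacterial RNA, -2.83 ± 0.34), Abca1 (a cholesterol exporter, -2.36 ± 0.37), Thbs1 (-3.16 ± 0.34) and Kcnj2 (-3.09 ± 0.34) fell. Genes classically induced by type I interferon had 0 of 30 members risen or fallen in both limma fits, with 4 higher and 1 lower at an unadjusted p under 0.05 and 0 called by edgeR (fry adjusted p = 0.97). With the block 6 of them were higher and 9 lower as deposited (fry adjusted p = 0.79), and 1 and 16 on rescaled values (0.023). Without replicate 3 in all groups the calls of Ccr2 (adjusted p = 0.15), Cx3cr1 (0.093) and Abca1 (0.068) were lost, and with untreated replicate 1 as the lone control those of Ccr2 (0.14) and Cx3cr1 (0.059). As deposited 3880 genes were higher and 290 lower (median log2 change 0.43), after rescaling 1292 and 1201. The total of 4170 became 2750 without untreated replicate 2, 2679 without IL-4 replicate 2 and 685 without replicate 3 in all groups.

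IFN-γ at 2 h raised Cxcl9, which encodes a chemokine for activated T cells, from 2.38 ± 1.22 to 711 ± 325 CPM (7.64 ± 0.67, adjusted p = 3.5e-07; chromosome 5, 92321347 to 92328079). Cxcl10, of the same chemokine family, rose from 22.4 ± 9.68 to 2923 ± 346 CPM (7.04 ± 0.31, adjusted p = 2.0e-10). Irf1, an early interferon regulatory factor, rose from 94.3 ± 24.3 to 1864 ± 516 CPM (4.28 ± 0.28, adjusted p = 1.7e-08; chromosome 11, 53770014 to 53778374). Socs1 (5.69 ± 0.22), Socs3 (4.73 ± 0.49), Batf2 (a bZIP factor, 4.87 ± 0.36), Ch25h (cholesterol 25-hydroxylase, 5.16 ± 0.58) and Irg1 (the itaconate-producing enzyme, also named Acod1, 6.09 ± 0.47) rose. Il4ra rose more than with IL-4, by log2 2.91 ± 0.26, a difference not tested here. Nos2, the inducible nitric oxide synthase, was at 2.80 ± 1.08 CPM at this time (1.84 ± 0.29, adjusted p = 1.7e-04). Guanylate-binding proteins with immunity-related GTPases had 17 of 18 up (fry adjusted p = 2.4e-09; adjusted p = 0.022 with an estimated correlation), such as Iigp1 (7.01 ± 0.38), Gbp5 (6.07 ± 0.46) and Gbp2 (5.68 ± 0.48). Reads of Gbp genes and of Iigp1 can be shared with near-identical copies, so each single value is uncertain. Markers of classical activation had 21 of 27 up (fry adjusted p = 6.4e-08; adjusted p = 0.053 with an estimated correlation). Type I interferon genes had 12 of 30 up, Zbp1 (2.33 ± 0.46) and Parp14 (2.14 ± 0.25) among them, and 23 adjusted over the list alone (fry adjusted p = 0.0041; adjusted p = 0.59 with an estimated correlation). MHC class I with antigen processing had 12 of 18 up, such as Tap1, a peptide transporter (2.39 ± 0.29), and Nlrc5, a class I transactivator (1.96 ± 0.30). As deposited 16 were higher adjusted over the list alone (fry adjusted p = 1.9e-05; adjusted p = 0.37 with an estimated correlation). JAK-STAT components had 14 of 24 up (fry adjusted p = 1.0e-05; adjusted p = 0.37 with an estimated correlation). Cytokines with chemokines had 12 of 29 up (fry adjusted p = 1.9e-05; adjusted p = 0.42 with an estimated correlation). MHC class II had 0 of 9 up in both limma fits (1 at an unadjusted p under 0.05, 0 by edgeR; fry adjusted p = 0.2) and 6 up with the block (0.013; 3 up on rescaled values, 0.0033), and its regulator Ciita was not called (0.85 ± 0.60, adjusted p = 0.44; 1.3e-05 with the block on rescaled values). Cd300lb (a myeloid activating receptor, -3.61 ± 0.24), S1pr1 (a sphingosine phosphate receptor, -3.56 ± 0.35), Gpr183 (an oxysterol receptor, -2.89 ± 0.35), Dusp6 (-2.03 ± 0.26) and Dusp1 (-1.97 ± 0.29), both MAP kinase phosphatases, fell. The call of Dusp6 was lost without replicate 3 in all groups (adjusted p = 0.064). As deposited 1598 genes were higher and 184 lower (median log2 change 0.27), after rescaling 1188 and 854. The block gave 2569 higher and 407 lower. The total of 1782 became 4035 without untreated replicate 1 and 646 without replicate 3 in all groups.

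At 4 h, IFN-γ raised Cxcl9 to 5451 ± 3833 CPM (10.35 ± 0.67, adjusted p = 4.1e-09) and Nos2 from 0.0363 ± 0.0629 to 99.2 ± 50.3 CPM (6.46 ± 0.29, adjusted p = 5.6e-11; chromosome 11, 78920787 to 78960254). Tnf, which encodes tumour necrosis factor, rose from 10.5 ± 3.68 to 732 ± 424 CPM (5.79 ± 0.56, adjusted p = 4.0e-07; chromosome 17, 35199381 to 35202007). Irf1 rose by log2 4.91 ± 0.28, Irf8, a myeloid interferon regulatory factor, by 2.93 ± 0.27 and Socs1 by 5.93 ± 0.22. Junb (AP-1, 2.53 ± 0.38) and Cebpb (C/EBPβ, 2.34 ± 0.35) rose too. All 18 guanylate-binding proteins and immunity-related GTPases rose, Iigp1 (8.68 ± 0.38) and Gbp4 (8.31 ± 0.23) included (fry adjusted p = 1.7e-11; adjusted p = 0.025 with an estimated correlation). Classical activation had 25 of 27 up, 26 adjusted over the list alone (fry adjusted p = 2.8e-10; adjusted p = 0.025 with an estimated correlation); Irg1 was among them (8.35 ± 0.47). All 18 members of MHC class I with antigen processing rose, such as Tap1 (3.67 ± 0.29) and Nlrc5 (3.16 ± 0.30) (fry adjusted p = 6.4e-08; adjusted p = 0.1 with an estimated correlation). MHC class II had 3 of 9 up, Ciita (3.40 ± 0.60) and the peptide-loading chain H2-DMa (1.69 ± 0.29) included (fry adjusted p = 0.023; adjusted p = 0.66 with an estimated correlation). Type I interferon genes had 20 of 30 up, for example Zbp1 (3.87 ± 0.46) and Ifit2 (3.25 ± 0.64), and 27 adjusted over the list alone (fry adjusted p = 9.6e-04; adjusted p = 0.44 with an estimated correlation). Cytokines with chemokines had 16 of 29 up, 19 higher and 1 lower adjusted over the list alone (fry adjusted p = 1.3e-07; adjusted p = 0.2 with an estimated correlation). Pattern recognition had 13 of 26 up and 2 down, 15 and 2 adjusted over the list alone (fry adjusted p = 6.3e-05; adjusted p = 0.44 with an estimated correlation). Tmem173 (the adaptor STING, 3.16 ± 0.21) and Nod1 (a sensor of bacterial peptidoglycan, 3.49 ± 0.32) were up. Glycolysis had 9 of 20 up and 1 down, 10 and 1 adjusted over the list alone (fry adjusted p = 0.0015; adjusted p = 0.55 with an estimated correlation). Slc2a1 (glucose carrier, 2.18 ± 0.15), Hk3 (hexokinase, 2.03 ± 0.29) and Pfkp (phosphofructokinase, 2.13 ± 0.37) rose. Immediate early genes had 11 of 21 up and 2 down, 13 and 2 adjusted over the list alone, with Zfp36, an mRNA-decay factor, at 3.40 ± 0.32 (fry adjusted p = 0.004; adjusted p = 0.55 with an estimated correlation). Chemokine receptors went both ways, 3 of 12 up and 5 down, with Cxcr4 (-3.02 ± 0.64) and Cx3cr1 (-3.03 ± 0.46) down (fry adjusted p = 0.69, and 0.048 on rescaled values). Both calls were lost without replicate 3 in all groups (adjusted p = 0.089 and 0.066). S1pr1 (-5.08 ± 0.35), Lhfpl2 (a tetraspan membrane protein, -4.86 ± 0.28), Cd300lb (-3.41 ± 0.24) and Nav2 (a cytoskeletal regulator, -3.44 ± 0.32) fell. As deposited 2014 genes were higher and 869 lower (median log2 change 0.10), after rescaling 2344 and 2103. The total of 2883 became 1057 without replicate 3 and 5220 without replicate 2 in all groups.

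**Figure D2:**
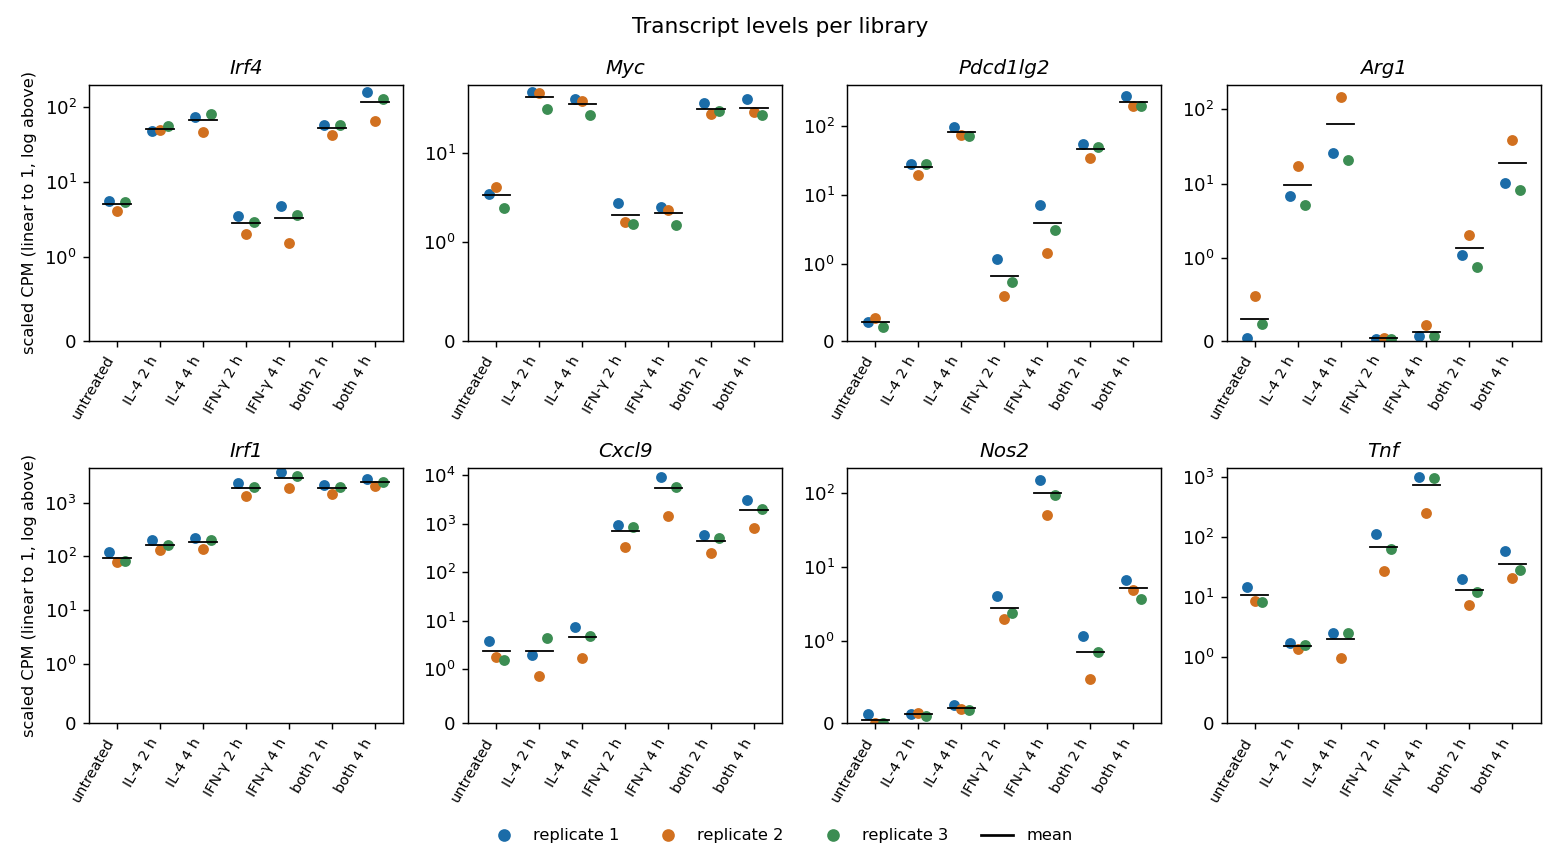
Rescaled CPM (y axis, linear up to 1 and log above) of 8 genes in the 7 groups (x axis); points are libraries coloured by replicate number, and the line is the group mean. Nos2 stood at 99.2 ± 50.3 CPM (mean ± SD) with IFN-γ for 4 h and at 5.13 ± 1.55 CPM with the combination, and Irf1 at 2915 ± 947 and 2422 ± 363 CPM.

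Both cytokines together, against untreated cells, gave genes of both responses. At 4 h Cxcl9 stood at 1976 ± 1136 CPM (9.05 ± 0.67, adjusted p = 1.4e-08) and Pdcd1lg2 at 220.1 ± 41.3 CPM (7.46 ± 0.31, adjusted p = 2.6e-11). Ccl24 (7.18 ± 0.54), Socs1 (7.10 ± 0.22), Irf1 (4.69 ± 0.28) and Irf4 (4.19 ± 0.31) rose. Serpina3g, a serine protease inhibitor whose reads are shared with near-identical neighbours and so uncertain, rose by log2 10.16 ± 0.32. Retnla was at 1.06 CPM, at least 44.65-fold over untreated cells with the same floor of 3 reads. S1pr1 (-5.62 ± 0.35) and Slc40a1 (-4.25 ± 0.33) fell. At 2 h Cxcl9 (7.03 ± 0.67), Socs1 (6.31 ± 0.22), Cish (5.90 ± 0.35), Irf4 (3.13 ± 0.31) and Ccl7 (6.22 ± 0.83) rose, and S1pr1 (-3.92 ± 0.35) fell. At 4 h all 18 guanylate-binding proteins and immunity-related GTPases rose (fry adjusted p = 5.6e-11; adjusted p = 0.063 with an estimated correlation), and 23 of 27 markers of classical activation (fry adjusted p = 3.9e-09; adjusted p = 0.094 with an estimated correlation). Alternative activation had 21 of 32 up (fry adjusted p = 1.2e-09; adjusted p = 0.063 with an estimated correlation), and MYC with ribosome biogenesis 25 of 35 (fry adjusted p = 2.1e-04; adjusted p = 0.52 with an estimated correlation). As deposited 2055 genes were higher and 308 lower at 2 h (median log2 change 0.29) and 2692 and 963 at 4 h (0.19). After rescaling these were 1408 and 1121 at 2 h, and 2518 and 2354 at 4 h; the block gave 3186 and 593 at 2 h. The 2 h total of 2363 became 4683 without untreated replicate 1 and 832 without replicate 3 in all groups. The 4 h total of 3655 became 1510 without replicate 3.

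Adding IL-4 to IFN-γ for 4 h lowered Tnf from 732 ± 424 to 35.3 ± 19.4 CPM (-4.21 ± 0.56, adjusted p = 5.9e-05) and Nos2 from 99.2 ± 50.3 to 5.13 ± 1.55 CPM (-3.93 ± 0.29, adjusted p = 9.9e-08). Irg1 fell from 2592 ± 1476 to 311 ± 102 CPM (-2.95 ± 0.47, adjusted p = 3.8e-04). Nfkbiz (-3.89 ± 0.43), Sgk1 (a serum-induced kinase, -3.34 ± 0.52) and Tlr2 (a receptor for bacterial lipoproteins, -3.65 ± 0.70) fell. So did Ccl5 (-3.56 ± 0.78), Ccl3 (-3.31 ± 0.62), Clec4e (a lectin receptor for glycolipids, -3.12 ± 0.55) and Nlrp3 (an inflammasome sensor, -2.87 ± 0.53). Ptgs2, cyclooxygenase-2, fell (-3.20 ± 0.79, adjusted p = 0.012), a call lost when single libraries were left out, with adjusted p = 0.09 without IFN-γ 4 h replicate 1, 0.076 without combination 4 h replicate 2 and 0.058 without combination 4 h replicate 3. Of other IFN-γ-induced genes, Cxcl9 was not called (-1.30 ± 0.67, adjusted p = 0.27; 0.0044 with the block on rescaled values). Nor were Irf1 (-0.22 ± 0.28, adjusted p = 0.77), Iigp1 (-0.22 ± 0.38, adjusted p = 0.85) and Gbp2 (-0.65 ± 0.48, adjusted p = 0.51). Serpina3g rose further (1.23 ± 0.32, adjusted p = 0.014). Genes of the IL-4 response rose in the presence of IFN-γ, among them Pdcd1lg2 to 220.1 ± 41.3 CPM (5.65 ± 0.31, adjusted p = 4.8e-09). Ccl24 (6.64 ± 0.54), Irf4 (4.76 ± 0.31), Tmem26 (4.14 ± 0.17), Arg1 (3.87 ± 0.60), Cdh1 (3.61 ± 0.19), Myc (3.39 ± 0.23), Socs2 (2.74 ± 0.23) and Mrc1 (1.43 ± 0.18) rose as well. Alternative activation had 18 of 32 up, 20 higher and 1 lower adjusted over the list alone (fry adjusted p = 5.1e-07; adjusted p = 0.0099 with an estimated correlation). MYC with ribosome biogenesis had 15 of 35 up, 24 adjusted over the list alone (fry adjusted p = 0.012; adjusted p = 0.31 with an estimated correlation). Cytokines with chemokines had 11 of 29 down and 1 up, 11 and 4 adjusted over the list alone (fry adjusted p = 0.023; adjusted p = 0.27 with an estimated correlation). Classical activation had 6 of 27 down and 1 up (fry adjusted p = 0.018; adjusted p = 0.27 with an estimated correlation). Chemokine receptors had 4 of 12 down, C5ar1 (-2.56 ± 0.19) and Ccrl2 (-2.79 ± 0.44) included, 5 adjusted over the list alone (fry adjusted p = 0.013; adjusted p = 0.27 with an estimated correlation). Immediate early genes had 8 of 21 down, such as Btg2 (-2.51 ± 0.43) and Dusp1 (-2.42 ± 0.29), and 10 adjusted over the list alone (fry adjusted p = 0.15; 0.049 on rescaled values and 0.031 with the block). Pattern recognition had 6 of 26 down and 2 up, 8 and 3 adjusted over the list alone (fry adjusted p = 0.15; 0.017 on rescaled values and 0.036 with the block). Guanylate-binding proteins with immunity-related GTPases had 3 of 18 down (fry adjusted p = 0.18). Type I interferon genes (0 of 30) and MHC class I (0 of 18) had no member called in both limma fits, with 1 higher each at an unadjusted p under 0.05 and 0 and 1 called by edgeR (fry adjusted p = 0.98 for both lists). With the block on rescaled values 1 higher and 1 lower of the former list, and 1 and 2 of the latter, were called.

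Of 1114 genes induced by IFN-γ at 4 h, 113 (10.1%) were lowered by IL-4, 48 raised and 953 not called. The IFN-γ libraries enter both calls, which favours lowered genes. After rescaling 170 of 989 (17.2%) were lowered, and the block gave 266. With the block on rescaled values 399 of 1036 (38.5%) were lowered and 131 raised. At 2 h 11 of 809 (1.36%) were lowered and 32 raised, after rescaling 12 of 532 (2.26%) and 31, and with the block 58 and 70. With the block on rescaled values 86 of 580 (14.8%) were lowered and 70 raised. Induced genes lowered at 2 h included Tnf (-2.17 ± 0.56, adjusted p = 0.042), Ifitm1 (an interferon-induced membrane protein, -1.69 ± 0.34, adjusted p = 0.0069), Prr5l (a partner of mTOR complex 2, -1.31 ± 0.23), Il13ra1 (an IL-13 receptor chain, -1.08 ± 0.18) and Dusp10 (-0.96 ± 0.17). The call of Tnf was lost with adjusted p = 0.25 without IFN-γ 2 h replicate 1, 0.14 without IFN-γ 2 h replicate 3, 0.18 without combination 2 h replicate 2 and 0.13 without combination 2 h replicate 3. That of Il13ra1 was lost with each of the 6 libraries of this contrast left out in turn, with adjusted p = 0.1 without IFN-γ 2 h replicate 1, 0.11 without IFN-γ 2 h replicate 2, 0.14 without IFN-γ 2 h replicate 3, 0.078 without combination 2 h replicate 1, 0.11 without combination 2 h replicate 2 and 0.17 without combination 2 h replicate 3. Without a filter on low values those of Tnf (0.087) and Il13ra1 (0.064) were lost, and in a fit to the groups of the contrast alone that of Tnf (0.15). Leaving out replicate 1 in all groups ended all 5 calls (0.23 for Tnf, 0.16 for Ifitm1, 0.14 for Prr5l, 0.1 for Il13ra1 and 0.054 for Dusp10). So did leaving out replicate 3 (1, 0.48, 0.41, 1 and 0.77 in the same order). These fits had no block, so differences between replicate numbers counted as error. With all libraries and the block on rescaled values, the adjusted p of the 5 genes was 9.4e-05, 1.3e-05, 2.6e-04, 7.6e-06 and 4.2e-04 in that order. Cxcl10, also induced, was not called at 2 h (-0.64 ± 0.31, adjusted p = 0.57). At 4 h its mean was lower with the combination, at 2226 ± 545 CPM against 7650 ± 3330 CPM with IFN-γ alone. At 2 h the combination held more Pdcd1lg2 (4.68 ± 0.31), Ccl24 (4.58 ± 0.54), Irf4 (3.79 ± 0.31), Myc (3.43 ± 0.23), Batf3 (3.05 ± 0.30), Cdh1 (2.89 ± 0.19) and P2ry1 (a nucleotide receptor, 2.65 ± 0.13) than IFN-γ alone. Arrdc3 was lower (-2.30 ± 0.23). Alternative activation had 13 of 32 up at 2 h, 14 adjusted over the list alone (fry adjusted p = 8.7e-05; adjusted p = 0.0029 with an estimated correlation). In the comparison of all genes, 447 were higher and 251 lower with the combination at 4 h, 675 and 675 after rescaling, and 842 and 655 with the block. The block on rescaled values turned the balance, with 1590 higher and 2115 lower. At 2 h there were 162 and 27, after rescaling 254 and 89, and with the block 366 and 172. Without replicate 1 of IFN-γ the 4 h total of 698 became 428, without its replicate 3 it became 459, and without replicates 1, 2 and 3 in all groups 265, 1602 and 127. The 2 h total of 189 became 104 and 91 without replicates 1 and 3 of IFN-γ, 110 and 102 without those of the combination, and 57, 439 and 23 without replicates 1, 2 and 3 in all groups. The 113 lowered genes became 60 and 75 without IFN-γ replicates 1 and 3, 75 without combination replicate 2, and 54, 213 and 14 without replicates 1, 2 and 3 in all groups. The 11 became 22 without untreated replicate 1, 5 and 4 without IFN-γ replicates 1 and 3, 6, 5 and 5 without combination replicates 1, 2 and 3, and 0, 26 and 0 without replicates 1, 2 and 3 in all groups. Without replicate 3 in all groups, with 2 libraries per group, the 4 h calls of Ptgs2 (adjusted p = 0.53), Serpina3g (0.2), Ccrl2 (0.16), Btg2 (0.065), Mrc1 (0.14), Tlr2 (0.22), Ccl5 (0.29), Ccl3 (0.24), Sgk1 (0.095), Irg1 (0.07), Clec4e (0.17) and Nlrp3 (0.22) were lost, and those of Tnf and Nos2 were not. Without replicate 1 those of Btg2 (0.062) and Mrc1 (0.059) were lost, without replicate 2 that of Serpina3g (0.057), and in a fit to the groups of the contrast alone those of Nlrp3 (0.052) and Ptgs2 (0.13).

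**Figure D3:**
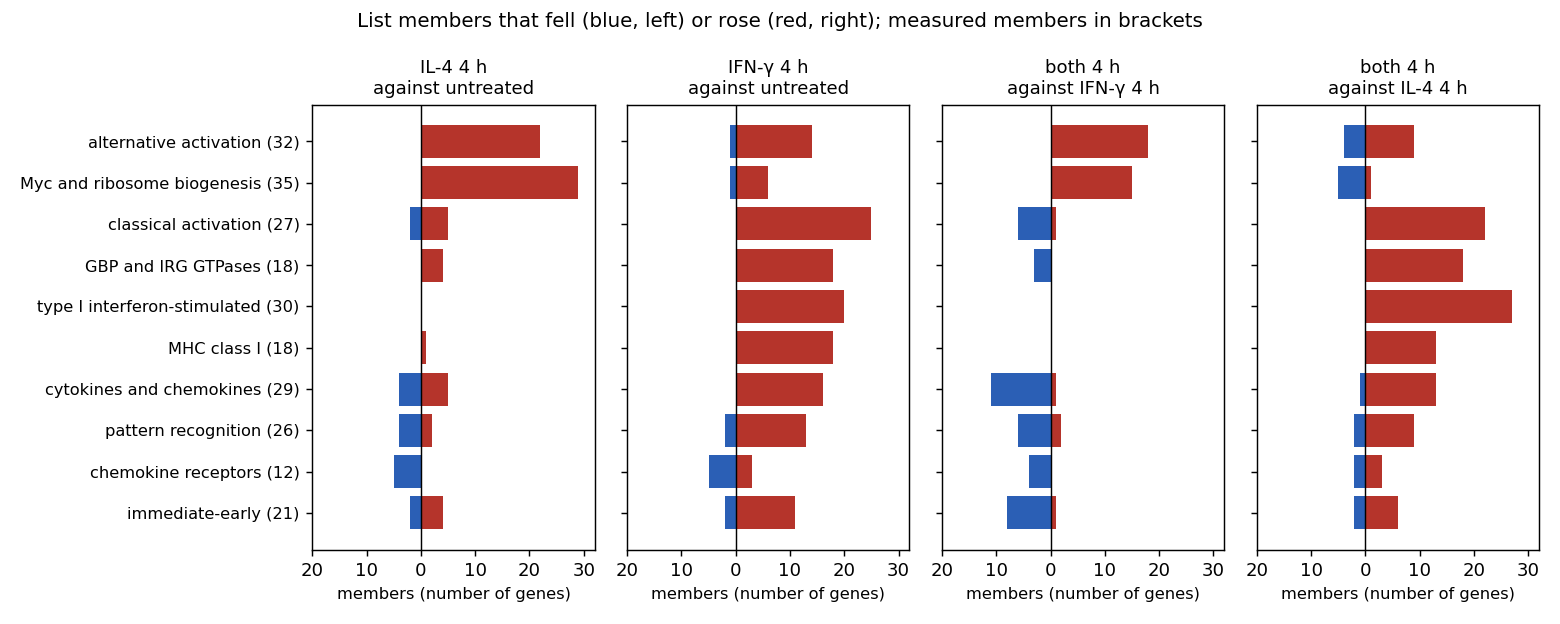
Members of 10 gene lists (y axis, number measured in brackets) that rose (right) or fell (left) in both fits (x axis, number of genes) in 4 contrasts at 4 h. With IL-4 added to IFN-γ, 18 of 32 markers of alternative activation rose and 11 of 29 cytokines and chemokines fell.

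Adding IFN-γ to IL-4 for 4 h lowered Retnla from 43.8 ± 4.17 to 1.06 ± 0.388 CPM (-4.46 ± 0.11, adjusted p = 5.8e-14) and Itgb3, the integrin β3 chain, from 97.8 ± 30.2 to 11.4 ± 3.08 CPM (-2.97 ± 0.38, adjusted p = 1.4e-05). Scn3a (a sodium channel, -3.09 ± 0.15), Abcd2 (a peroxisomal fatty acid carrier, -3.23 ± 0.32) and S1pr1 (-3.56 ± 0.35) fell. Arg1 was called only as deposited (-1.72, adjusted p = 0.042; rescaled -1.46 ± 0.60, adjusted p = 0.079; 0.0052 with the block). Even that call was lost, with adjusted p = 0.26 without IL-4 4 h replicate 2, 0.15 without combination 4 h replicate 1 and 0.17 without combination 4 h replicate 3. Mrc1 (-0.15 ± 0.18, adjusted p = 0.58) and Myc (-0.15 ± 0.23, adjusted p = 0.69) were not called, and Pdcd1lg2 rose (1.43 ± 0.31, adjusted p = 0.002), as did Socs1 (2.21 ± 0.22). Cxcl9 (8.41 ± 0.67), Cxcl10 (8.19 ± 0.31), Iigp1 (7.75 ± 0.38), Gbp2 (7.09 ± 0.48), Irf1 (3.74 ± 0.28) and Nos2 (2.35 ± 0.29) rose. All 18 guanylate-binding proteins and immunity-related GTPases rose (fry adjusted p = 5.7e-10; adjusted p = 0.0062 with an estimated correlation). So did 22 of 27 markers of classical activation (fry adjusted p = 8.7e-08; adjusted p = 0.012 with an estimated correlation). Type I interferon genes had 27 of 30 up (fry adjusted p = 0.0015; adjusted p = 0.13 with an estimated correlation), and MHC class I 13 of 18 (fry adjusted p = 9.5e-06; adjusted p = 0.064 with an estimated correlation). Alternative activation had 9 of 32 up and 4 down (fry adjusted p = 0.45). At 2 h the first of these lists had 16 of 18 up (fry adjusted p = 1.0e-07; adjusted p = 0.005 with an estimated correlation) and classical activation 17 of 27 (fry adjusted p = 1.5e-05; adjusted p = 0.022 with an estimated correlation). Type I interferon genes had 10 of 30 (fry adjusted p = 0.026; adjusted p = 0.21 with an estimated correlation) and MHC class I 6 of 18 up (fry adjusted p = 0.0075; adjusted p = 0.2 with an estimated correlation). Cxcl10 (7.52 ± 0.31), Cxcl9 (7.09 ± 0.67), Iigp1 (6.24 ± 0.38), Gbp2 (4.95 ± 0.48) and Irf1 (3.47 ± 0.28) rose at 2 h. Cd300lb (-2.83 ± 0.24), S1pr1 (-2.85 ± 0.35), Ptgir (the prostacyclin receptor, -2.20 ± 0.19), Dusp7 (-2.26 ± 0.25), Tmem26 (-1.97 ± 0.17) and Klf4 (-1.82 ± 0.28) fell. Pdcd1lg2 at 4 h (adjusted p = 0.15) and Klf4 at 2 h (0.06) were not called without replicate 3 in all groups. Of 1026 genes induced by IL-4 at 4 h, IFN-γ lowered 340 (33.1%) and raised 113, and after rescaling it lowered 124 of 370 (33.5%) and raised 71. With the block on rescaled values it lowered 187 of 397 (47.1%) and raised 117. The share of IFN-γ-induced genes lowered by IL-4 at 4 h was 10.1% as deposited and 38.5% in that fit. The distance between the 2 directions therefore depended on the fit. The IL-4 libraries enter both calls, which favours lowered genes. At 2 h 102 of 540 (18.9%) were lowered and 59 raised, after rescaling 68 of 242 (28.1%) and 40, and with the block 195 were lowered. With the block on rescaled values 112 of 272 (41.2%) were lowered and 78 raised. In the comparison of all genes 978 were higher and 2109 lower at 4 h (median log2 change -0.27), after rescaling 1806 and 1712. At 2 h 563 were higher and 378 lower (median log2 change -0.11), after rescaling 997 and 677, and with the block 924 and 977. The 4 h total of 3087 became 1200, 5136 and 580 without replicates 1, 2 and 3 in all groups. The 2 h total of 941 became 580 and 563 without IL-4 replicates 1 and 3, 585 without combination replicate 1, and 356, 1794 and 209 without replicates 1, 2 and 3 in all groups. The 340 lowered genes became 609 without untreated replicate 1, and 177 and 64 without replicates 1 and 3 in all groups. The 102 became 171 without untreated replicate 1, 62 and 63 without IL-4 replicates 1 and 3, 60 and 64 without combination replicates 1 and 2, and 40 and 18 without replicates 1 and 3 in all groups.

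From 2 h to 4 h, Retnla rose under IL-4 from 1.49 ± 0.0874 to 43.8 ± 4.17 CPM (4.17 ± 0.11, adjusted p = 3.5e-13). Scn3a (3.05 ± 0.15), Tmem26 (2.31 ± 0.17) and Flt1 (a receptor for vascular growth factors, 1.74 ± 0.19) rose, and Arg1 was not called (2.20 ± 0.60, adjusted p = 0.064; 9.3e-04 with the block on rescaled values). Under IFN-γ Nos2 rose from 2.80 ± 1.08 to 99.2 ± 50.3 CPM (4.62 ± 0.29, adjusted p = 4.1e-08), and Clic5 (a chloride channel protein, 5.30 ± 0.17), Ptgs2 (5.60 ± 0.79), Tnf (3.40 ± 0.56) and Gbp4 (3.58 ± 0.23) rose. Ciita rose by log2 2.55 ± 0.60, adjusted p = 0.0074, lost with adjusted p = 0.096 without IFN-γ 2 h replicate 2, 0.085 without IFN-γ 4 h replicate 1 and 0.07 without IFN-γ 4 h replicate 3. Cxcl9 rose by 2.71 ± 0.67, adjusted p = 0.0091, lost with adjusted p = 0.078 without IFN-γ 2 h replicate 2, 0.1 without IFN-γ 4 h replicate 1 and 0.066 without IFN-γ 4 h replicate 3. Nav2 (-3.22 ± 0.32), Ahr (the aryl hydrocarbon receptor, -2.77 ± 0.34) and Zdhhc14 (a palmitoyltransferase, -3.08 ± 0.45) fell. Under the combination Flt1 (3.49 ± 0.19), Il12rb1 (an IL-12 receptor chain, 3.56 ± 0.19), Clic5 (3.67 ± 0.17), Arg1 (2.80 ± 0.60) and Nos2 (1.70 ± 0.29) rose, and Nav2 (-3.56 ± 0.32), Slc40a1 (-2.92 ± 0.33) and Tlr13 (-2.24 ± 0.34) fell. Without replicate 3 in all groups the calls of Flt1 under IL-4 (adjusted p = 0.12), of Ptgs2 (0.071), Tnf (0.15) and Zdhhc14 (0.079) under IFN-γ, and of Arg1 (0.13), Nos2 (0.05) and Tlr13 (0.077) under the combination were lost, as was that of Arg1 without replicate 1 (0.13). Guanylate-binding proteins with immunity-related GTPases had 14 of 18 up under IFN-γ (fry adjusted p = 8.3e-05; adjusted p = 0.038 with an estimated correlation) and 13 of 18 under the combination (fry adjusted p = 1.9e-04; adjusted p = 0.091 with an estimated correlation). For MHC class I these were 11 of 18 (fry adjusted p = 0.0018; adjusted p = 0.062 with an estimated correlation) and 12 of 18 (fry adjusted p = 0.0015; adjusted p = 0.12 with an estimated correlation). For classical activation they were 15 of 27 (fry adjusted p = 3.2e-04; adjusted p = 0.038 with an estimated correlation) and 10 of 27 (fry adjusted p = 0.0087; adjusted p = 0.15 with an estimated correlation). Alternative activation had 3 of 32 up under IL-4, 10 higher and 2 lower adjusted over the list alone (fry adjusted p = 0.0033; adjusted p = 0.28 with an estimated correlation). Under the combination it had 7 up and 2 down (fry adjusted p = 0.0087; adjusted p = 0.15 with an estimated correlation). As deposited 50 genes were higher at 4 h and 25 lower under IL-4, 359 and 556 under IFN-γ (median log2 change -0.17), and 377 and 586 under the combination (-0.10). After rescaling these were 146 and 171, 1115 and 901, and 1079 and 1004, and with the block 224 and 238, 812 and 1755, and 850 and 1569. Without replicates 1, 2 and 3 in all groups, the total of 75 under IL-4 became 24, 365 and 7, the 915 under IFN-γ became 190, 3065 and 51, and the 963 under the combination 227, 2278 and 73. Single libraries moved the IFN-γ total to 594, 502 and 474 (without 2 h replicates 1, 2 and 3) and to 394 and 455 (without 4 h replicates 1 and 3). They moved the combination total to 601, 633 and 556 (without 2 h replicates 1, 2 and 3) and to 515 and 542 (without 4 h replicates 1 and 3).

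The interaction was tested directly as the combined log2 change minus the sum of the single ones. At 2 h it was negative for Socs1, which stood at 0.890 ± 0.396 CPM in untreated cells, 86.2 ± 29.1 with IL-4, 95.5 ± 10.6 with IFN-γ and 147 ± 8.97 with both (-4.88 ± 0.30, adjusted p = 2.0e-07). Cish (-3.41 ± 0.50, adjusted p = 0.0046), Klf4 (-2.31 ± 0.40, adjusted p = 0.013) and Il4ra (-1.90 ± 0.36, adjusted p = 0.032) followed at 2 h. At 4 h it was negative for Socs1 (-3.72 ± 0.30, adjusted p = 4.1e-06), Cish (-2.94 ± 0.50, adjusted p = 0.0042), Nos2 (-4.12 ± 0.41, adjusted p = 2.7e-05) and Cd40, a costimulatory receptor (-3.09 ± 0.53, adjusted p = 0.0044). Positive values were seen for Lhfpl2 (2.97 ± 0.40, adjusted p = 6.0e-04) and Zfp961 (1.95 ± 0.21, adjusted p = 5.2e-05). Lhfpl2 stood at 340 ± 35.9 CPM in untreated cells, 58.8 ± 9.31 with IL-4, 11.8 ± 6.46 with IFN-γ and 15.3 ± 4.34 with both. Its positive value thus marks a fall smaller than the sum of the single falls, not a joint rise. Zfp961, a zinc-finger gene, stood at 9.95 ± 0.326 CPM in untreated cells, 10.9 ± 0.593 with IL-4, 14.6 ± 2.15 with IFN-γ and 63.9 ± 5.91 with both. Without replicate 3 in all groups the calls of Cish (adjusted p = 0.33 at 2 h and 0.23 at 4 h), Klf4 (0.65), Il4ra (0.68), Cd40 (0.38), Lhfpl2 (0.76) and Zfp961 (0.76) were lost, and without replicate 1 those of Klf4 (0.08), Il4ra (0.14), Lhfpl2 (0.19) and Zfp961 (0.22). Fits to the groups of the contrast alone lost Il4ra (0.057), Lhfpl2 (0.051) and Zfp961 (0.057), and untreated replicate 1 as the lone control lost Klf4 (0.087) and Il4ra (0.069). JAK-STAT components had 4 of 24 negative at 2 h (fry adjusted p = 0.03; adjusted p = 0.57 with an estimated correlation) and 4 at 4 h (fry adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation). Alternative activation had 5 of 32 negative at 2 h (fry adjusted p = 0.036; adjusted p = 0.62 with an estimated correlation) and 3 at 4 h (fry adjusted p = 0.006; adjusted p = 0.69 with an estimated correlation). Classical activation had 4 of 27 negative at 4 h (fry adjusted p = 0.0081; adjusted p = 0.64 with an estimated correlation) and guanylate-binding proteins with immunity-related GTPases 2 of 18 (fry adjusted p = 0.012; adjusted p = 0.64 with an estimated correlation). On rescaled values the fry adjusted p was 0.29 for JAK-STAT components and 0.29 for alternative activation at 2 h. At 4 h it was 0.17 for JAK-STAT components, 0.062 for classical activation, 0.11 for guanylate-binding proteins with immunity-related GTPases and 0.022 for alternative activation, the only 1 of these 6 calls kept. As deposited 44 genes were negative and 1 positive at 2 h (median -0.40), and 178 and 8 at 4 h (median -0.38). After rescaling these were 31 and 11, and 91 and 86, and with the block 294 and 32, and 952 and 108. The 2 h total of 45 became 582 without untreated replicate 1, and 6, 69 and 1 without replicates 1, 2 and 3 in all groups. The 4 h total of 186 became 2267 and 115 without untreated replicates 1 and 3, 95, 102 and 104 without IL-4 replicates 1, 2 and 3, 90 and 83 without IFN-γ replicates 1 and 3, and 94 and 98 without combination replicates 2 and 3. Without replicates 1, 2 and 3 in all groups it became 50, 395 and 9.

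The series title names opposing programmes, and the directions of the single responses at 4 h were set side by side. Itgb3 rose with IL-4 (2.19 ± 0.38) and fell with IFN-γ (-1.75 ± 0.38), as did P2ry1 (1.73 ± 0.13 and -1.90 ± 0.13). Nfkbiz (-2.68 ± 0.43 and 2.00 ± 0.43) and Tnfaip2, a gene induced by tumour necrosis factor (-2.03 ± 0.44 and 2.02 ± 0.44), fell with IL-4 and rose with IFN-γ. Tnf fell with IL-4 as well (-1.96 ± 0.56, adjusted p = 0.017), with adjusted p = 0.084 without untreated replicate 1 and 0.096 without IL-4 4 h replicate 2. Leaving out replicate 3 in all groups, the calls of Tnfaip2 were lost with IL-4 (adjusted p = 0.15) and IFN-γ (0.058), as was that of Tnf with IL-4 (0.17). Without replicate 1 those of Itgb3 with IFN-γ (0.085) and Tnf with IL-4 (0.067) were lost. With untreated replicate 1 as the lone control that of Tnfaip2 with IFN-γ was lost (0.054). As deposited, 174 genes were called in opposite directions, 133 up with IL-4 and down with IFN-γ against 296.3 from the call rates alone, and 41 the other way against 51.3. In the same direction there were 900 up (686.7 from the rates) and 141 down (22.1). After rescaling 371 genes were opposite and 999 the same, and the block gave 496 opposite. The rescaled balance was turned, with 162 up with IL-4 and down with IFN-γ (238.8 from the rates) and 209 the other way (247.4). In the same direction 434 were then up (266.1 from the rates) and 565 down (221.9). Across genes the log2 changes had a covariance of 0.121 (correlation 0.229). Simulations gave 0.054 (0.502) with untreated libraries shared and 0.020 (0.497) with replicate differences kept too. Simulated correlations hold noise alone, so only covariances compare, and the real one was higher. Genes are not independent replicates. The 174 became 349 and 100 without untreated replicates 2 and 3, 107 without IL-4 replicate 3, 115 without IFN-γ replicate 3, and 35, 642 and 8 without replicates 1, 2 and 3 in all groups.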

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

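The tests of the interaction with the single-cytokine effects kept, of reads taken by ribosomal RNA, of the untreated state, of ribosomal RNA as a source of the cell-cycle difference and of granulocyte precursors were chosen only after the results were seen.

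Results that differed between time points or between the combination and the sum of the single cytokines were looked at again because the difference itself was tested. Between 2 h and 4 h, 75 genes differed under IL-4, 915 under IFN-γ and 963 under the combination. The interaction differed from 0 for 45 genes at 2 h and 186 at 4 h. At 2 h its log2 values were -4.88 for Socs1, -3.41 for Cish, -2.31 for Klf4 and -1.90 for Il4ra. At 4 h they were -3.72 for Socs1, -2.94 for Cish, -4.12 for Nos2, -3.09 for Cd40, 2.97 for Lhfpl2 and 1.95 for Zfp961. For Socs1, Cish and Il4ra the mean CPM under the combination was above that under either single cytokine. For Nos2 and Cd40 at 4 h and Klf4 at 2 h it lay below that of the stronger single cytokine. For Zfp961 it was above that under either single cytokine. For Lhfpl2 it lay between them, with all treated means below that of untreated cells.

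Each comparison of a pair of groups has 10 splits of its 6 libraries, too few for a share under 0.05. The real split was the 1 with the most called genes in each of these 13 comparisons. Against untreated cells, IL-4 gave 1903 genes at 2 h and 4170 at 4 h (highest other split 0 for both), IFN-γ 1782 (0) and 2883 (1850), and the combination 2363 (0) and 3655 (5). The combination against IFN-γ gave 189 (0) and 698 (5), and against IL-4 941 (0) and 3087 (0). From 2 h to 4 h the real values were 75 (1), 915 (0) and 963 (0). The split with 1850 genes set untreated replicates 1 and 3 with IFN-γ replicate 2 against the rest; like the real split it parted the libraries of every replicate number, and such a count points to a structure of the samples. The induced genes lowered by the other cytokine had the same limit: 11 and 113 for IFN-γ (highest other split 0 and 5), and 102 and 340 for IL-4 (0 and 0). For the interaction, 100 regroupings of the 12 libraries were drawn, the real one included. At 2 h 9 of them gave as many genes as the real 45 (highest 936), and at 4 h 13 gave as many as the real 186 (highest 3693). These regroupings turn the effects of the single cytokines into interactions and break the pairing by replicate number. Their high counts therefore decide nothing about chance. With the sum of the single effects kept and the residuals exchanged among libraries of 1 replicate number, 2 of 100 exchanges, the real one included, gave as many genes at 2 h (highest other 46) and 2 at 4 h (highest other 469). Both shares are under 0.05, which argues against chance for the counts as deposited, narrowly so with 1 exchange above each real count. In the deposited values the median interaction over all genes was -0.395 at 2 h and -0.379 at 4 h, against -0.003 and -0.014 after rescaling. Ribosomal RNA in the untreated libraries could give such counts too. The exchanges were not repeated on rescaled values, so they do not separate an interaction from that shift.

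Ribosomal RNA was high in untreated replicates 2 and 3, and 93% of the genes called for IL-4 at 4 h were higher in the deposited values. With Rn45s and Lars2 removed and each library set to the same total again, 60.4% of those calls were higher, and 26% of those for IFN-γ at 4 h, so reads taken by ribosomal RNA could make up part of the excess but the rest stays open. The untreated state as the source of the ribosomal RNA is argued against by untreated replicate 1, which 12 of the 18 treated libraries exceeded in Rn45s. Carry-over of RNAs without a poly(A) tail stays open. Rmrp, at 0.691, 221 and 80.1 CPM as deposited in untreated replicates 1, 2 and 3, and Rpph1, at 0.691, 167 and 60.4 CPM, go with it but were seen before the test. The 29 other small non-coding RNAs were higher by a median log2 of 0.402 in replicates 2 and 3, 13 of them by at least 1, which decides neither way. A general effect of treatment on all genes was not tested.

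Genes induced by IFN-γ that rose further from 2 h to 4 h were lowered more by IL-4 than the others. With the rise taken in replicate 1, 2 or 3 and the fall in the other libraries, Spearman's rho across 1106, 703 and 956 induced genes was -0.309, -0.219 and -0.364, and the late genes changed by a median log2 of -0.40, -0.51 and -0.51, the other induced genes by -0.10, -0.24 and -0.09. The IFN-γ 4 h libraries shared by both differences would give values nearer 0, but the weakest rho, -0.219, passed the bound set for it by less than the spread of the 3 values, so this stays open. With the size of the IFN-γ induction held fixed, the weakest partial rho was -0.165 (-0.290 and -0.330 in the others), and the size of the induction stays open as well. A preference of IL-4 for the later part of the response may lie behind the pattern and cannot be told apart from these explanations.

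Cell-cycle genes were high in replicate 2 of every group, for example Top2a at 11.7, 301 and 104 CPM in untreated replicates 1, 2 and 3. Ribosomal RNA in the untreated library is argued against as the source, since the mitosis list had its highest median in replicate 2 in 6 of 6 treated groups. Granulocyte precursors are argued against too, since Mpo, Elane and Prtn3 reached at most 7.11 CPM in a replicate 2 library. The labels name no batch, animal or day behind the replicate numbers, and no other explanation was tested.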

How the results depend on the processing

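The block with rescaled values, untreated replicate 1 as the lone control and the rescaled list tests were chosen only after the data were seen. Of 5000 recomputed values for 252 pairs of a named gene and a comparison, 4840 kept their direction and their side of the threshold, 127 lost the threshold, 21 gained it and 12 reversed, and 186 of the named results kept their side under every setting tried. Without replicate 3 in all groups 54 calls were lost and without replicate 1 18, each with 2 libraries left per group. The fits with libraries left out had no block, so differences between replicate numbers counted as error in them. The results with reversed values had small log2 changes as deposited, 0.100 for Stat6 and -0.120 for both Iigp1 and Irf1. Stat6 with IL-4 at 4 h was -0.397 with median-ratio scaling and with scaling and block, -0.362 with quantile normalization, -0.383 with edgeR, -0.393 with DESeq2, -0.294 with untreated replicate 1 as the lone control, -0.186 without untreated replicate 2 and -0.121 without replicate 2 in all groups (-0.186 to 0.298 over the libraries left out). Iigp1, both cytokines against IFN-γ at 4 h, was 0.005 with quantile normalization, 0.028 without IFN-γ 4 h replicate 1 and 0.111 without combination 4 h replicate 2 (-0.359 to 0.111 over the libraries left out). Irf1 in that comparison was 0.002 without IFN-γ 4 h replicate 1 (-0.319 to 0.002). The cause was not tested.

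Counts named below moved by more than 1.5 times from the reported ones, which were IL-4 at 2 h 1903, IL-4 at 4 h 4170, IFN-γ at 2 h 1782, IFN-γ at 4 h 2883, both at 2 h 2363, both at 4 h 3655, both against IFN-γ at 2 h 189, both against IFN-γ at 4 h 698, both against IL-4 at 2 h 941, both against IL-4 at 4 h 3087, time under IL-4 75, time under IFN-γ 915, time under both 963, interaction at 2 h 45, interaction at 4 h 186, IFN-γ-induced lowered at 2 h 11, IFN-γ-induced lowered at 4 h 113, IL-4-induced lowered at 2 h 102, IL-4-induced lowered at 4 h 340, opposed genes 174 and lists 120. The cause was not tested unless stated. Median-ratio scaling gave IL-4 at 2 h 982, IL-4 at 4 h 2493, IFN-γ at 4 h 4447, both against IFN-γ at 2 h 343, both against IFN-γ at 4 h 1350, both against IL-4 at 2 h 1674, time under IL-4 317, time under IFN-γ 2016, time under both 2083, IFN-γ-induced lowered at 4 h 170, IL-4-induced lowered at 4 h 124 and opposed genes 371. Quantile normalization gave IL-4 at 2 h 1069, IL-4 at 4 h 2696, both against IFN-γ at 2 h 368, both against IFN-γ at 4 h 1219, both against IL-4 at 2 h 1755, time under IL-4 406, time under IFN-γ 1753, time under both 2061, IL-4-induced lowered at 4 h 144 and opposed genes 390. With edgeR the counts were IL-4 at 2 h 990, IL-4 at 4 h 2516, IFN-γ at 4 h 4439, both against IFN-γ at 2 h 354, both against IFN-γ at 4 h 1383, both against IL-4 at 2 h 1709, time under IL-4 291, time under IFN-γ 2095, time under both 2116, IFN-γ-induced lowered at 4 h 178, IL-4-induced lowered at 4 h 136 and opposed genes 399. With DESeq2 they were IL-4 at 2 h 1250, IFN-γ at 4 h 4697, both against IFN-γ at 2 h 501, both against IFN-γ at 4 h 1702, both against IL-4 at 2 h 1987, time under IL-4 605, time under IFN-γ 2428, time under both 2549, interaction at 2 h 104, interaction at 4 h 802, IFN-γ-induced lowered at 2 h 23, IFN-γ-induced lowered at 4 h 233, IL-4-induced lowered at 4 h 148 and opposed genes 485. The replicate block gave IL-4 at 2 h 4338, IFN-γ at 2 h 2976, both at 2 h 3779, both against IFN-γ at 2 h 538, both against IFN-γ at 4 h 1497, both against IL-4 at 2 h 1901, both against IL-4 at 4 h 4953, time under IL-4 462, time under IFN-γ 2567, time under both 2419, interaction at 2 h 326, interaction at 4 h 1060, IFN-γ-induced lowered at 2 h 58, IFN-γ-induced lowered at 4 h 266, IL-4-induced lowered at 2 h 195 and opposed genes 496. Scaling and block together gave IL-4 at 2 h 2936, IFN-γ at 2 h 4374, IFN-γ at 4 h 7220, both at 2 h 4992, both at 4 h 7622, both against IFN-γ at 2 h 1179, both against IFN-γ at 4 h 3705, both against IL-4 at 2 h 3777, both against IL-4 at 4 h 6377, time under IL-4 2282, time under IFN-γ 5170, time under both 5355, interaction at 2 h 329, interaction at 4 h 1680, IFN-γ-induced lowered at 2 h 86, IFN-γ-induced lowered at 4 h 399, IL-4-induced lowered at 4 h 187, opposed genes 1196 and lists 201.

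A required log2 change of at least 1 gave IL-4 at 2 h 580, IL-4 at 4 h 1165, IFN-γ at 2 h 926, IFN-γ at 4 h 1513, both at 2 h 1149, both at 4 h 1806, both against IFN-γ at 4 h 435, both against IL-4 at 2 h 546, both against IL-4 at 4 h 1247, time under IFN-γ 447 and time under both 479, fewer by its construction. Fits to the groups of the contrast only, with fewer libraries, gave IL-4 at 2 h 521, IL-4 at 4 h 1344, IFN-γ at 2 h 1005, IFN-γ at 4 h 1747, both at 2 h 1338, both at 4 h 2326, interaction at 2 h 22 and interaction at 4 h 53. Untreated replicate 1 as the lone control, assumed to vary like the other groups, gave IL-4 at 2 h 452, IL-4 at 4 h 1263, interaction at 2 h 17, interaction at 4 h 97 and IL-4-induced lowered at 4 h 194. Without a filter on low values IFN-γ-induced lowered at 2 h 7 moved, and with a mean of at least 5 CPM time under IL-4 47 and IFN-γ-induced lowered at 2 h 7. Genes selected at the other time point gave IFN-γ-induced lowered at 4 h 51 and IL-4-induced lowered at 4 h 192. These are out of 809 and 540 genes induced at 2 h, against 113 of 1114 and 340 of 1026 induced at 4 h. The counts alone therefore do not show a lower share. That selection shares no library with the second contrast, but it also takes other genes, so it does not measure the selection noise alone. Induction by any called increase gave IL-4-induced lowered at 4 h 926. Camera with an estimated correlation left 14 of the 120 pairs of list and contrast that fry called.

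Leaving out 1 library, or 1 replicate number in all groups, gave these lowest and highest counts: IL-4 at 2 h 251 to 5760, IL-4 at 4 h 685 to 6245, IFN-γ at 2 h 646 to 4035, IFN-γ at 4 h 1057 to 5220, both at 2 h 832 to 4683, both at 4 h 1510 to 4885, both against IFN-γ at 2 h 23 to 439, both against IFN-γ at 4 h 127 to 1602, both against IL-4 at 2 h 209 to 1794, both against IL-4 at 4 h 580 to 5136, time under IL-4 7 to 365, time under IFN-γ 51 to 3065, time under both 73 to 2278, interaction at 2 h 1 to 582, interaction at 4 h 9 to 2267, IFN-γ-induced lowered at 2 h 0 to 26, IFN-γ-induced lowered at 4 h 14 to 213, IL-4-induced lowered at 2 h 18 to 171, IL-4-induced lowered at 4 h 64 to 609 and opposed genes 8 to 642. The lowest came without replicate 3 in all groups in every case but IFN-γ-induced genes lowered at 2 h, where replicate 1 did the same.

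Depth limits only the lowest values. One read was at most 0.0346 CPM, below the 1 CPM required for a test.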

Other observations

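Further gene lists were tested at 4 h. Interferon regulatory factors had 5 of 8 members up with IFN-γ, among them Irf7 (1.99 ± 0.43) and Irf2 (1.39 ± 0.19), while Irf4 was not called (-0.56 ± 0.31, adjusted p = 0.17; fry adjusted p = 1.7e-06; adjusted p = 0.26 with an estimated correlation). With IL-4 2 of 8 rose, Irf4 and Irf1 (0.95 ± 0.28, adjusted p = 0.02), 4 adjusted over the list alone (fry adjusted p = 5.6e-04; 0.084 on rescaled values; adjusted p = 0.8 with an estimated correlation). The call of Irf1 was lost without replicate 3 in all groups (adjusted p = 0.11) and with untreated replicate 1 as the lone control (0.18). AP-1 with C/EBP factors had 10 of 20 up with IFN-γ, such as Batf2 (6.22 ± 0.36), Maff (3.58 ± 0.67) and Batf3 (2.59 ± 0.30) (fry adjusted p = 0.0012; adjusted p = 0.55 with an estimated correlation), and 3 up and 1 down with IL-4, among them Batf3, Batf (0.93 ± 0.21) and Fos (-2.27 ± 0.39; lost without replicate 3 in all groups, adjusted p = 0.11), 4 and 1 adjusted over the list alone (fry adjusted p = 0.11; 0.023 with the block). Immediate early genes had 4 of 21 up and 2 down with IL-4 (fry adjusted p = 0.52). Lipid handling went both ways: 3 of 20 up and 4 down with IFN-γ (fry adjusted p = 0.86; 9.5e-07 lower with the block on rescaled values), where Ch25h rose (5.82 ± 0.58) and Abca1 fell (-2.06 ± 0.37; lost without replicate 3 in all groups, adjusted p = 0.085), and 2 up and 2 down with IL-4 (fry adjusted p = 0.4; 1.1e-05 lower). Cholesterol synthesis had 2 of 23 up with IFN-γ, Pmvk (2.41 ± 0.23) and Ebp (0.95 ± 0.13) (fry adjusted p = 0.45), and 0 with IL-4 in both limma fits (1 at an unadjusted p under 0.05, 0 by edgeR; fry adjusted p = 0.3), where the block called 18 higher as deposited (0.0025) and 1 on rescaled values (0.69). Macrophage identity genes had 5 of 24 up and 3 down with IFN-γ (fry adjusted p = 0.37), with Fcgr1 up (2.36 ± 0.20) and the scavenger receptor Cd163 down (-2.17 ± 0.20), and 2 up and 2 down with IL-4 (fry adjusted p = 0.4; 0.02 lower with the block on rescaled values), with Fcgr2b up (2.56 ± 0.41). Adhesion with matrix had 6 of 26 up with IFN-γ, Itga4 (2.29 ± 0.33) and Itgav (1.91 ± 0.17) included, 7 adjusted over the list alone (fry adjusted p = 0.0099; adjusted p = 0.81 with an estimated correlation), and 3 up and 2 down with IL-4, 6 and 2 adjusted over the list alone (fry adjusted p = 0.15; 0.0021 lower with the block on rescaled values). Heat shock with stress had 3 of 19 up and 2 down with IFN-γ (fry adjusted p = 0.48) and 3 up and 1 down with IL-4 (fry adjusted p = 0.3; 0.0057 lower with the block on rescaled values). Hmox1, heme oxygenase, fell with both (-1.87 ± 0.32 and -1.79 ± 0.32), the call with IL-4 lost without replicate 3 in all groups (adjusted p = 0.098). Glycolysis had 1 of 20 up with IL-4 (fry adjusted p = 0.23; 0.016 lower with the block on rescaled values).

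DNA replication (24 measured) had 0 called in both limma fits with either single cytokine at 4 h. At an unadjusted p under 0.05 there was 1 higher with IL-4 and 1 lower with IFN-γ, and edgeR called 0 and 2 (fry adjusted p = 0.97 and 0.72). Mitosis (24 measured) had 0 by limma without the block, at an unadjusted p under 0.05 and by edgeR alike (fry adjusted p = 0.97 and 0.91). With the block, members were called. DNA replication had 3 higher and 3 lower with IL-4 and 1 and 7 with IFN-γ as deposited (fry adjusted p = 0.88 and 0.27), and 0 and 9, and 1 and 15, on rescaled values (0.044 and 0.011). Mitosis had 1 higher and 0 lower with IL-4 and 0 and 4 with IFN-γ as deposited (0.79 and 0.48), and 0 and 3, and 0 and 7, on rescaled values (0.16 and 0.085). MHC class II had 0 of 9 called with IL-4 in both limma fits (2 higher at an unadjusted p under 0.05, 0 by edgeR; fry adjusted p = 0.3), and 4 higher with the block (0.032; 2 higher and 1 lower on rescaled values, 0.46).

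Markers of other cell types were measured as a background. Of the neutrophil list 2 genes are also in another list, of the dendritic list 1, of the osteoclast list 2, and of the stromal, B cell, T and NK cell, erythroid, and mast cell with basophil lists 0. Neutrophil markers had 1 of 14 up with IFN-γ, Cxcr2 (0.55 ± 0.16; fry adjusted p = 0.32 and 0.031 with the block), and 0 with IL-4 in both limma fits (2 at an unadjusted p under 0.05, 0 by edgeR; fry adjusted p = 0.63). With the block 3 were higher with IL-4, and on rescaled values 1 higher and 5 lower. The call of Cxcr2 was lost in a fit to the groups of the contrast alone (adjusted p = 0.2) and without replicate 1 (0.13) or 3 (0.089) in all groups. Dendritic cell markers had 3 of 5 up with IFN-γ, Batf3, Clec9a (1.56 ± 0.23) and Kmo (1.34 ± 0.31; lost without replicate 3 in all groups, adjusted p = 0.1, and with untreated replicate 1 as the lone control, 0.35) (fry adjusted p = 2.9e-05; adjusted p = 0.27 with an estimated correlation), and 2 up with IL-4 at a median log2 change of -0.04 as deposited (fry adjusted p = 5.7e-04; adjusted p = 0.86 with an estimated correlation). Osteoclast markers had 1 of 6 down with IFN-γ (fry adjusted p = 0.084; 0.0013 on rescaled values and 0.017 with the block) and 1 up with IL-4, Itgb3 in both cases, 2 adjusted over the list alone (fry adjusted p = 0.0017; 0.097 on rescaled values; adjusted p = 0.86 with an estimated correlation). Stromal markers had 1 of 7 up with IL-4, Postn (0.60 ± 0.20, adjusted p = 0.037; fry adjusted p = 0.38), and 0 with IFN-γ by limma, at an unadjusted p under 0.05, by edgeR and with the block (fry adjusted p = 0.95). The call of Postn was lost with edgeR (adjusted p = 0.052), with untreated replicate 1 as the lone control (0.1) and without replicate 3 in all groups (0.15). Fewer than 3 genes were measured for mitochondrially encoded genes (0), histones (2), B cells (1), T and NK cells (2), erythroid cells (0) and mast cells with basophils (2), and these lists were not tested. Of their genes Hdc, histidine decarboxylase, rose with IFN-γ (2.53 ± 0.15, adjusted p = 1.9e-09), as did Lck, a lymphocyte kinase (3.10 ± 0.30, adjusted p = 3.9e-07).

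Gene groups also differed by replicate number within the groups. The median log2 deviation of the mitosis list from its group mean was -1.90, 2.095 and -0.29 in replicates 1, 2 and 3. Replicate 2 was also higher in DNA replication (1.00), type I interferon genes (0.51) and cholesterol synthesis (0.43), and lower in MHC class II (-0.68, against 0.59 in replicate 1). Neutrophil markers lay at 0.38 in replicate 1 and -0.57 in replicate 3.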
